A study of Danio rerio with 4 samples.

How the data were processed

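Messenger RNA was sequenced from dissected zebrafish cardiac ventricles taken 4 days after injury, in 2 libraries from ccn2a mutants and 2 from wild type, with a stranded poly(A) kit, per the labels' protocols. The sample titles write the mutants as ccn2a-/- and the time as 4 dpci. The labels number the samples within each genotype but do not say whether a sample was 1 heart or a pool of hearts, so p-values measure only the spread between these samples, which may be technical. STAR 2.4.0a, featureCounts 1.4.5-p1 from Subread and DESeq2 1.6.2 are named in the submitters' processing notes, without their settings, and the strand setting of the counting is not given in the sources used here. The same notes name the genome build GRCz10 (danRer10). The largest coordinate in the deposited table is 78048911 on chromosome 4, which lies beyond the end of that chromosome in GRCz10, so the coordinates look like those of a later build. Coordinates are therefore given as the table prints them, with the build unsettled.

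The deposited table gave 19875 genes, 18981 of them protein-coding, with a whole-number score in each library, a gene's read count that the authors had divided by a size factor and rounded. This reading came from the values: low values in a library fell on a regular spacing, as rounding after division leaves them. The spacing gave a factor of 0.874 and 0.946 for mutant replicates 1 and 2, and of 0.952 and 1.32 for wild-type replicates 1 and 2. In the 3 libraries with a factor below 1, between 99.7% and 99.9% of the values below 600 lay on that spacing. For wild-type replicate 2 the spacing is finer than whole numbers, so every value lies on it, and its factor rests on how often each value occurs. Median-of-ratios factors computed on the table itself lay between 1.0089 and 1.0124, as for values already scaled. In 4 simulated libraries of 19875 genes, with factors below and above 1, the factor was recovered with an error of 0.0%. The wild-type replicate 2 factor is above 1, so different read counts share a rounded value there and whole reads could not be recovered. Each value multiplied by its library's factor gave approximate depths of 18.8, 18.1, 17.2 and 21.5 M reads for mutant replicates 1 and 2 and wild-type replicates 1 and 2. No gene was 0 in all 4 libraries and the smallest sum of a gene over them was 4, so genes with fewer reads had been left out before deposit. No per-sample column was left unused.

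Because the values are not raw counts, genotypes were compared with limma 3.58.1 (limma-trend) in R 4.3.3, on log2(value + 1), with genotype as the term and no block. Fold changes are on that scale, which understates changes of low genes. Genes were kept at a mean of 10 or more over the 4 libraries, which left 16730, and 2-sided p-values were adjusted with the Benjamini-Hochberg method to a threshold of 0.05. With 2 libraries per group the fit had 2 residual degrees of freedom per gene, to which limma added 4.01 from the other genes. Values were read with the R package data.table (1.17.8), and figures and summary tables were made in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

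A set of 35 gene lists, covering pathways, cell types of the heart and tissues that a dissection can carry along, was fixed before the data were examined. Of 1225 places in those lists, 1105 matched a gene of the table by symbol or by a current symbol for its Ensembl ID, and 1024 were tested. Lists were compared with limma's camera at a preset correlation of 0.01 between genes, with ccn2a left out. Camera was repeated with an estimated correlation, and fry, a rotation test of a list on its own, was run on the same lists. Pathways annotated in the deposited table were tested in the same way after the other results had been seen.

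The genes named in the text followed a rule fixed before the data were examined. It took ccn2a and its paralog, then 12 genes higher and 12 lower in the mutant with a mean of 50 or more, non-overlapping groups and a symbol that is not a clone name. Since none passed the threshold, the rule took those with the smallest unadjusted p. It also took up to 4 members of each list with the smallest p, and up to 6 genes near ccn2a that passed, of which there were none. Among its symbols, 211 belong to more than 1 Ensembl gene, and named genes among them carry their Ensembl ID. An item that the rule named is not reported here.

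The fit was tested on simulated data for ccn2a mutant against wild type, in 20 runs over 16730 genes with negative-binomial noise and 67 genes changed 2-fold, 67 changed 4-fold and 66 changed 8-fold, drawn from genes with a mean of 50 or more. It called 3.81% of the 2-fold, 67.8% of the 4-fold and 87.3% of the 8-fold changes, and 0.00998% of the unchanged genes. The median residual SD was 0.267 in the simulated data and 0.283 in the real data, on the log2 scale. A shift of 0.5 in a list of 40 genes was found in 20 of 20 runs, with 0 calls among 700 tests of unchanged lists. In those simulations genes varied independently.

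The alternatives were pseudocounts of 0.5 and 5, no filter or a mean of 50 or more, TMM rescaling, quantile normalisation, the replicate number as a block, a robust prior, an adjusted p of 0.1, a 2-fold minimum, lists without shared members, and each library left out in turn. Where 1 library was left in a group, it was assumed to vary like the other group. A count of genes at unadjusted p under 0.05 and limma voom on approximate reads were added after the data were seen. Tests on whole reads were not run.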

Results

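The series asked how the transcriptome of the injured zebrafish ventricle depends on ccn2a, which encodes a secreted matricellular protein of the CCN family. RNA was profiled 4 days after injury in 2 ccn2a mutant and 2 wild-type ventricle libraries. Approximate depth was 18.8 and 18.1 M reads in mutant replicates 1 and 2, and 17.2 and 21.5 M in wild-type replicates 1 and 2. Values are size-factor-normalised read counts, rounded by the authors. The most similar pair of libraries crossed the genotypes: mutant replicate 2 and wild-type replicate 1, with a Pearson r across genes of 0.970. That r was 0.955 between the mutants and 0.959 between the wild types, and genes are not independent replicates. The first principal component held 64.1% of the variance and put the genotypes on opposite sides, at 78.9 and 16.4 for mutant replicates 1 and 2 and at -24.7 and -70.6 for wild-type replicates 1 and 2. Transcripts of the mitochondrial genome made up 14.7% and 13.6% of the values in the mutants, 13.4% in wild-type replicate 1 and 7.66% in wild-type replicate 2. No pair of libraries agreed within sampling noise, with a chi-square per gene of 24.4 or more for each of the 6 pairs.

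The ccn2a transcript itself (symbol ctgfa in the table, ENSDARG00000042934, chromosome 20, 25340814 to 25343490) was still detected in the mutants. Its normalised count was 3070 and 1473 in mutant replicates 1 and 2, against 4737 and 4411 in wild type, or 2272 ± 1129 against 4574 ± 231 (mean ± SD, n = 2 each). The log2 fold change was -1.10 (SE 0.355), a level 2.15-fold lower, which did not pass the threshold (limma, adjusted p = 0.381). Without mutant replicate 2 the log2 fold change was -0.57. The labels do not give the lesion and a gene-level value does not show it, so the value is a weak check of the genotype labels. The paralog ccn2b (symbol ctgfb, chromosome 19) had 255 and 54 in the mutants against 55 and 83 in wild type (adjusted p = 0.596), and its direction reversed to -0.32 without mutant replicate 1.

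Beyond ccn2a, the genes with the clearest separation included several that were much lower in both mutant libraries. The chymotrypsinogen gene ctrb1 was at 98 and 82 in the mutants against 704 and 1179 in wild type, 10.1-fold lower. A gene named ANXA1, after the annexin that binds phospholipids, was at 2 and 2 against 87 and 116. The monooxygenase-like gene moxd1 was at 293 and 341 against 1179 and 1285, 3.88-fold lower, and the granulin gene grn1 was at 285 and 378 against 6351 and 2475. The neutrophil chemokine cxcl8a was at 34 and 29 against 125 and 136. The hyaluronan-binding gene tnfaip6 was at 627 ± 5.66 against 1426 ± 60.8. The others on the lower side were myo15b, slc24a2, vcla (ENSDARG00000098695), MYRFL, ppp1r14ba and tppp, with log2 fold changes from -6.61 for MYRFL to -1.88 for ppp1r14ba. MYRFL rests on 138 and 823 in the wild types against 5 and 1 in the mutants. ANXA1, myo15b and MYRFL return under the other observations, where gene copies that differ between the stocks stay open as an explanation.

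On the higher side, the muscle ubiquitin ligase gene fbxo32 was at 619 ± 173 in the mutant and 162 ± 19.1 in wild type, 3.75-fold higher. Its neighbour on chromosome 16 in the table, klhl38b, was at 247 ± 63.6 against 77.5 ± 10.6. The hyaluronan and proteoglycan link gene hapln1b was at 3619 ± 719 against 1181 ± 317. The corticosteroid-inactivating enzyme gene hsd11b2 was at 9261 ± 688 against 3563 ± 819, and the chemokine receptor gene cxcr3.1 at 593 and 666 against 196 and 89. The EGF-family ligand gene hbegfb was at 1288 and 985 against 498 and 500. Also on this side were lpin1, c6 (ENSDARG00000093052), tob1a, the pyruvate kinase gene pkmb, tmem88a and mpped2, with log2 fold changes from 1.03 for pkmb to 1.76 for mpped2.

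None of these 24 genes passed. Of 16730 genes tested, 0 passed an adjusted p of 0.05 with limma-trend (smallest adjusted p = 0.207), and 0 passed with limma voom on approximate reads. At an unadjusted p under 0.05 there were 2145 genes with limma-trend, 986 higher and 1159 lower in the mutant, where chance gives 836.5, and 2452 with voom. The other splits of the 4 libraries into pairs, which ignore genotype, gave 117 and 338 with limma-trend. The count was 648 without mutant replicate 1 and 448 without wild-type replicate 2. The genotypes did not overlap at 8753 genes, or 52.3%, where chance gives 33.3%. With 4 libraries the smallest p of an exact permutation test of genotype is 0.333.

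**Figure D1:**
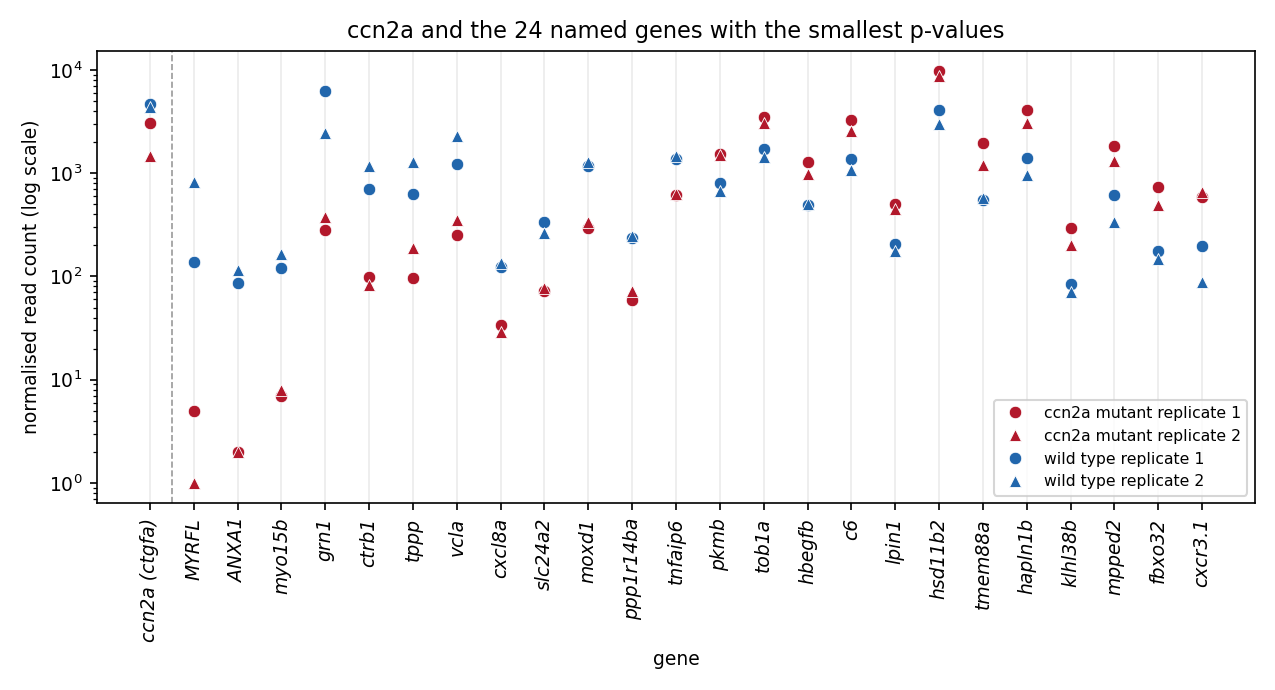
Normalised read count (log axis) of ccn2a and of the 12 lower and 12 higher genes with the smallest unadjusted p, with 1 point per library. Mutant (red) and wild-type (blue) points do not overlap at any of these genes, as the rule for naming them required, and none passed the adjusted threshold.

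Gene lists were therefore read as groups. With the preset correlation, 14 of 35 lists passed, 10 higher and 4 lower in the mutant. With an estimated correlation 0 passed (smallest adjusted p = 0.679, unadjusted p under 0.05 for 1 list), and 0 passed with fry (smallest adjusted p = 0.376, unadjusted p under 0.05 for 4 lists). Camera with an estimated correlation gave that same adjusted p to lists with unlike unadjusted p. Those were 0.043 for endothelium, 0.064 for the cell cycle, 0.33 for erythrocytes and 0.37 for oxidative phosphorylation. It rests on the 2 residual degrees of freedom, so a list that did not pass it is not thereby shown to be unchanged. With the preset correlation, the split of replicates numbered 1 against those numbered 2 called 6 lists, and that of mutant replicate 1 and wild-type replicate 2 against the others called 12. Of the 14, the former also called the cell cycle, erythrocyte, oxidative phosphorylation, fatty acid oxidation and ribosomal lists, and the latter the collagen, matrix glycoprotein, interferon, oxidative phosphorylation, growth factor, heat shock and ribosomal lists. Among the 14, the sarcomere, endothelium, glycolysis and immediate early lists were called in neither of those splits, a difference that was not itself tested. In the account that follows, rose and fell refer to the preset-correlation test.

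Proliferation genes fell in the mutant ventricles. Of 39 cell cycle genes, 37 were lower and 2 higher in the mutant, with a median log2 fold change of -0.95 (camera, adjusted p = 2.19e-13), while adjusted p = 0.679 with an estimated correlation. The mutant libraries lay below both wild types at 28 of the 39 genes. No member passed over all genes, and 14 passed adjusted over the list alone, all lower. The condensin genes smc2 and smc4 had log2 fold changes of -1.21 (SE 0.235) and -1.12 (SE 0.263), and the cyclin A gene ccna2 had -0.95 (SE 0.228). In normalised counts, smc2 was at 510 and 630 in the mutants against 1141 and 1514, the condensin gene ncapg at 285 and 335 against 543 and 709, and ccna2 at 284 and 371 against 635 and 622. The list passed without each library in turn and under quantile normalisation. It also passed in the split that put both replicates numbered 1 against both numbered 2, with a median of -0.27 (adjusted p = 0.0359), but not in the remaining split (median -0.21, adjusted p = 0.684).

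**Figure D2:**
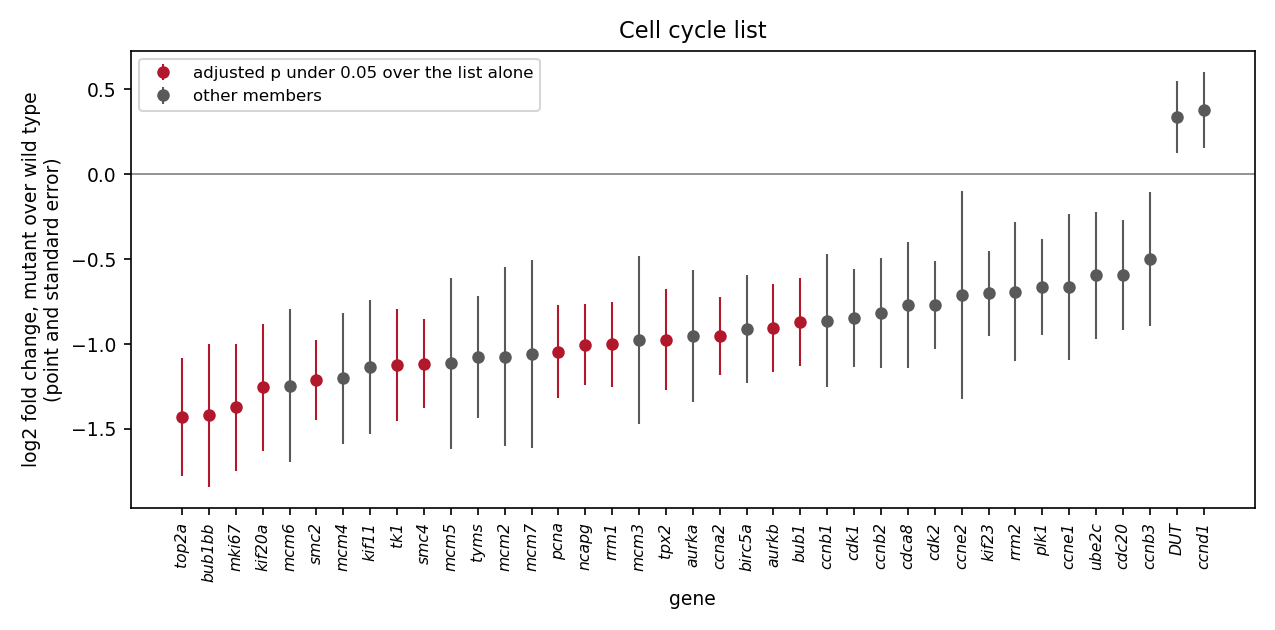
Log2 fold change of each tested cell cycle gene, mutant over wild type, with its standard error; red marks the 14 genes that passed adjusted over the list alone. Of the 39 genes, 37 lie below 0.

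The lists of matrix glycoproteins and of collagens, which build the provisional and collagenous scar, fell. Of 39 matrix glycoprotein and proteoglycan genes, 27 were lower and 12 higher (median -0.34, adjusted p = 0.0075, or 0.679 with an estimated correlation), and 4 passed adjusted over the list alone. Those were tnc (162 and 267 in the mutants against 503 and 922), cthrc1a (221 and 145 against 409 and 510) and thbs2b (113 and 149 against 308 and 327) on the lower side, and hapln1b on the higher. Of 21 collagen genes, 17 were lower and 4 higher (median -0.26, adjusted p = 0.0485, or 0.679 with an estimated correlation). They included col11a1b (3036 and 2252 against 4154 and 4911), col12a1b (3624 and 4016 against 5697 and 9105), col4a1 (518 and 1949 against 2565 and 2809) and col8a2. The collagen I genes col1a1a, col1a1b and col1a2, named after their values were seen, had log2 fold changes of 0.05, -0.02 and -0.03, with overlapping groups. Over the collagen list, mutant replicate 1 lay between the wild types, at a median of 0.03 from each gene's mean, against -0.29 in mutant replicate 2 and -0.0046 and 0.29 in the wild types. Both calls ended without mutant replicate 2 (medians -0.37 and -0.13) and without wild-type replicate 2 (medians -0.10 and -0.09), and the collagen call ended with voom on approximate reads (adjusted p = 0.0521). The collagen median was -0.55 without mutant replicate 1 and -0.47 under quantile normalisation.

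The remaining matrix and signalling lists around ccn2a did not pass. The other CCN genes had 5 of 7 members higher (median 0.40, adjusted p = 0.308), with cyr61l2 at 1372 and 781 against 565 and 543, cyr61l1 at 129 and 38 against 34 and 23, cyr61 at 7597 and 4822 against 4372 and 4839, and wisp2 at 16 and 13 against 26 and 21. Of 34 TGF-beta pathway genes 22 were higher (median 0.22, adjusted p = 0.0689). In that list inhbb was at 596 and 465 against 331 and 143, id3 at 739 and 637 against 473 and 397, and tgfbr3 at 6 and 32 against 90 and 66. The 12 YAP/TEAD targets had a median of 0.27 but a mean of -0.08 (adjusted p = 0.573), with amotl2b, amotl2a, AXL and tead1a the members with the smallest p. Collagen crosslinking and folding enzymes had a median of -0.24 (16 of 22 lower, adjusted p = 0.308), with loxl1 at 5748 and 4334 against 3225 and 1949 and tgm2b at 7440 and 4539 against 9692 and 10167. There p4ha1a and tgm2a had log2 fold changes of -0.76 and 2.71. Matrix proteases and inhibitors had a median of -0.14 (16 of 25 lower, adjusted p = 0.264), with adamts1 at 197 and 259 against 398 and 470, mmp15a at 111 and 473 against 780 and 954, and timp4.3 at 156 and 104 against 86 and 45.

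Contractile and energy genes rose in the mutant ventricles. Ventricular sarcomere and calcium-handling genes were higher at 27 of 30 (median 0.41, adjusted p = 0.00118, or 0.679 with an estimated correlation), with tcap at 8200 and 7085 against 4211 and 2209, ldb3b at 28359 and 16389 against 12679 and 10082, smyd1b at 3440 and 3085 against 1548 and 2316, and the alpha-actinin gene actn2b going the other way, at 25669 and 36704 against 47615 and 58445. Fatty acid oxidation genes were higher at 28 of 35 (median 0.49, adjusted p = 5.3e-06, or 0.679 with an estimated correlation), among them cpt1b, the muscle carnitine palmitoyltransferase, at 2971 and 2049 against 1237 and 1111, acadvl at 32430 and 22227 against 15296 and 9797, acsl1b at 12700 and 9876 against 5099 and 2196, and acadl. Oxidative phosphorylation genes of the nuclear genome were higher at 71 of 74 (median 0.38, adjusted p = 3.69e-10, or 0.679 with an estimated correlation), with cox6c at 8392 and 7650 against 5989 and 4127, and with cox8b, ndufs7 and uqcrb beside it. That list was called in both other splits too, and led the split of replicates numbered 1 against those numbered 2 (adjusted p = 5.35e-15). Glycolysis genes were higher at 31 of 40 (median 0.36, camera, adjusted p = 0.0075, or 0.679 with an estimated correlation). Among them, pkmb was at 1531 and 1502 against 811 and 679, and tpi1b at 19555 and 18653 against 13456 and 10776. The gene pdk2a, whose kinase inhibits the pyruvate dehydrogenase complex, was at 13128 and 5743 against 2958 and 1611. On the lower side, pfkla was at 62 and 238 against 330 and 424. Cytosolic ribosomal protein genes were higher at 76 of 76 (median 0.26, adjusted p = 2.29e-06, or 0.737 with an estimated correlation), none reaching an unadjusted p under 0.05, with rps21, rpl10a, rps14 and rpl32 between 0.38 and 0.45. Without mutant replicate 1 the medians were 0.15 for oxidative phosphorylation, 0.11 for ribosomal proteins and 0.31 for fatty acid oxidation, and without mutant replicate 2 they were 0.63, 0.41 and 0.69, all still called. Under quantile normalisation the sarcomere, glycolysis and ribosomal calls ended (medians 0.13, 0.23 and 0.02) and the oxidative phosphorylation median was 0.22. The share of mitochondrial-genome transcripts ranked the libraries in the same order as these lists, but it set wild-type replicate 2 apart, at 7.66%. The oxidative phosphorylation list instead set mutant replicate 1 apart, at a median of 0.43 from each gene's mean. It was at -0.04 in mutant replicate 2 and at -0.09 and -0.27 in wild-type replicates 1 and 2. Cardiac stress and dedifferentiation genes did not pass (median -0.08, 15 of 27 lower, adjusted p = 0.827), although the skeletal actin gene acta1a was at 4062 and 8333 against 19280 and 30538. In the same list nkx2.5 was at 3538 and 2483 against 2122 and 1416, gata5 at 5547 and 3530 against 2855 and 2663, and hand2 at 6012 and 3883 against 3402 and 2768.

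**Figure D3:**
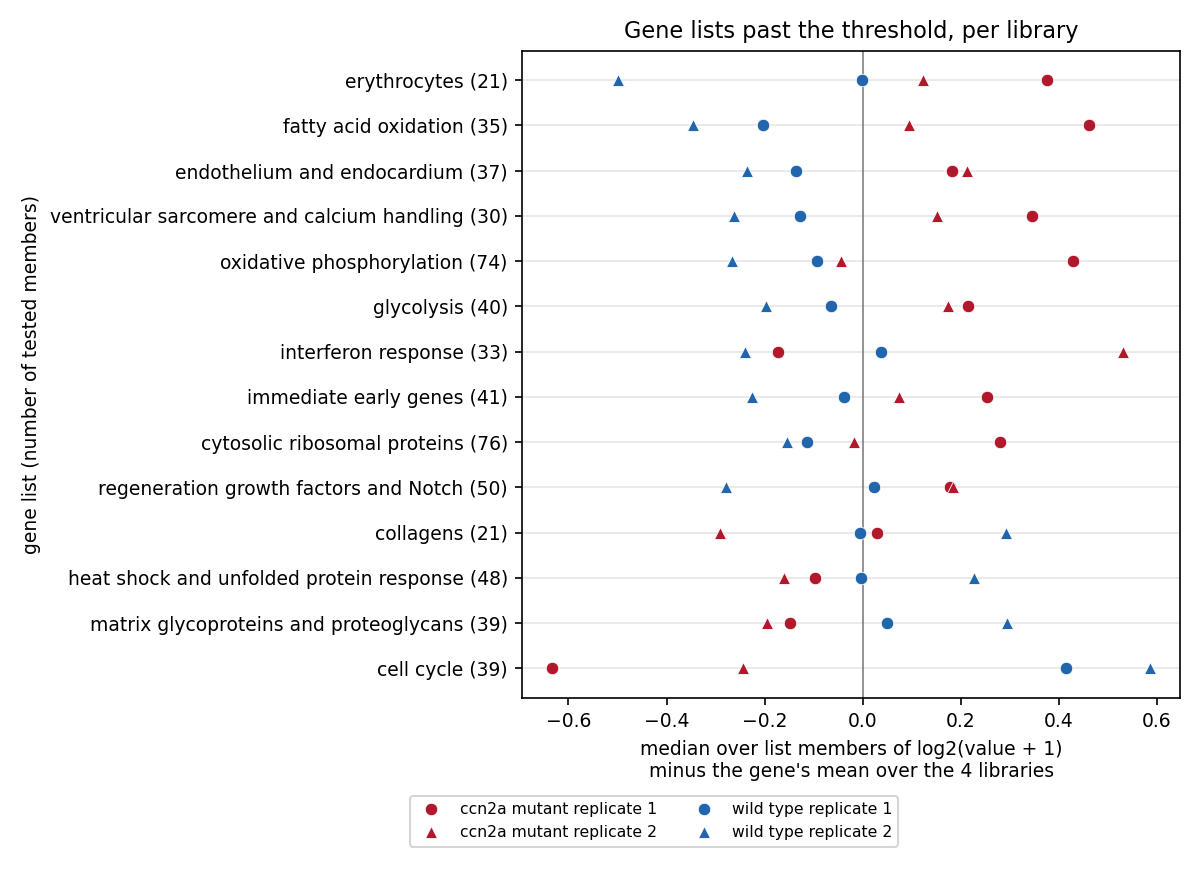
For each of the 14 lists past the threshold, the median over its members of log2(value + 1) minus the gene's mean over the 4 libraries, with 1 point per library. The mutant (red) and wild-type (blue) points of the cell cycle list lie apart, at -0.63 and -0.24 against 0.41 and 0.59, whereas mutant replicate 1 lies between the wild types for interferon response, at -0.17, and for collagens.

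Endothelial and erythrocyte genes also rose. Endothelial and endocardial genes were higher at 28 of 37 (median 0.42, adjusted p = 4.58e-04, or 0.679 with an estimated correlation), and under quantile normalisation the median was 0.28 with the call kept. They included the tight junction gene cldn5b at 1789 and 1560 against 927 and 551, the fenestral diaphragm genes plvapa at 692 and 337 against 174 and 164 and plvapb at 1000 and 1021 against 608 and 604, and the transcription factor gene fli1a at 3808 and 3083 against 2331 and 2103. Erythrocyte genes were higher at 16 of 21 (median 0.57, adjusted p = 0.0075, or 0.679 with an estimated correlation), with alas2, which starts haem synthesis, at 9125 and 5595 against 4091 and 3224, the band 3 gene slc4a1a at 6346 and 4682 against 3240 and 2890, cahz at 8137 and 7713 against 5170 and 4211, and uros. That call ended without wild-type replicate 2 (median 0.43, adjusted p = 0.0695). Thrombocyte genes did not pass (median 0.30, adjusted p = 0.189), with itga2b at 1203 and 1221 against 743 and 478, ptgs1, tubb1 and f13a1b.

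Immune lists were mixed. Interferon response genes were higher at 26 of 33 (median 0.31, adjusted p = 0.0222, or 0.737 with an estimated correlation). The call ended without mutant replicate 2 (median 0.07) and without wild-type replicate 2 (median 0.21), and the median was 0.66 without mutant replicate 1. It led the split of mutant replicate 1 and wild-type replicate 2 against the others, with an adjusted p of 1.14e-08, smaller than by genotype. Its members with the smallest p were gbp3 at 149 and 270 against 429 and 492, cmpk2 at 78 and 147 against 44 and 36, irf7 at 371 and 760 against 340 and 166, and the class I gene mhc1uba at 13154 and 21993 against 5161 and 486, a member of a family whose close copies can share reads. Macrophage genes did not pass (21 of 33 lower, median -0.30, adjusted p = 0.0801), with grn1 passing adjusted over the list alone, mfap4 at 419 and 645 against 1343 and 916, c1qb at 2435 and 2755 against 3667 and 4490, and csf1ra at 132 and 660 against 1090 and 926. Neutrophil genes did not pass (median -0.13, adjusted p = 0.464), with cfbl, at 652 and 721 against 1312 and 1393, passing adjusted over the list alone, mpx at 77 and 138 against 193 and 208, and alox5b.3 and cpa5 higher. Inflammatory cytokine genes had a median of 0.03 and a mean of -0.31 (adjusted p = 0.428), with cxcl8a passing adjusted over the list alone, saa at 10 and 27 against 81 and 417, cebpb at 2806 and 1895 against 2800 and 4227, and il4r.1 (ENSDARG00000102583) at 291 and 387 against 430 and 611. Complement and coagulation genes had a median of 0.15 and a mean of -0.08 (adjusted p = 0.827), with c7b, at 37 and 42 against 137 and 119, and c3a.1, at 152 and 286 against 623 and 644, passing adjusted over the list alone, and with f3a and f13a1b also lower. Lymphocyte genes did not pass (median 0.27, adjusted p = 0.224), with gata3 at 210 and 184 against 107 and 98, cd4-1 at 26 and 43 against 128 and 76, nkl.1 and cd28.

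Other cardiac cell types and tissues carried along in dissection gave no call. Fibroblast genes had a median of -0.09 (16 of 28 lower, adjusted p = 0.127), with tnc, fap at 77 and 72 against 169 and 344, thy1 at 263 and 74 against 520 and 925, and prrx1a at 224 and 277 against 410 and 414. Epicardial genes had a median of -0.12 and a mean of 0.00329 (adjusted p = 0.827), with fn1a at 18468 and 18406 against 29145 and 46681, jam2b at 332 and 256 against 176 and 111, lxn and adma. Smooth muscle, pericyte and outflow tract genes had a median of -0.01 (adjusted p = 0.827), with cspg4 at 41 and 95 against 142 and 236, elnb, mfap4 and rgs5a. Atrial genes had a median of 0.24 (adjusted p = 0.322), with smtnl1 at 468 and 790 against 320 and 123, cmlc1, nr2f2 and gnai1. Outside the heart, the medians were -0.29 for epithelium and gill (adjusted p = 0.151; epcam, cldnb, krt4 and krt5), 0.30 for skeletal muscle (adjusted p = 0.188; myod1, ryr1b, pvalb2 and actn3b) and 0.44 for liver and plasma proteins (adjusted p = 0.827; c3a.1, which passed adjusted over the list alone, apoa2, rbp4 and tfa). The exocrine pancreas and gut list had 6 of 8 members higher (median 0.90, adjusted p = 0.391; gcga and cpa5 among them), while ctrb1, which passed adjusted over the list alone, and amy2a were lower.

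Growth and stress signalling lists passed with small medians. Regeneration growth factor and Notch genes were higher at 33 of 50 (median 0.18, adjusted p = 0.0276, or 0.679 with an estimated correlation), with hbegfb, the Notch target her6 at 1043 and 1056 against 629 and 481, fgf17 at 1153 and 688 against 405 and 516, and igf1 on the lower side at 5 and 14 against 44 and 54. The call ended without mutant replicate 2 (median 0.31) and without wild-type replicate 2 (median 0.05), and the median was 0.27 without mutant replicate 1, 0.44 without wild-type replicate 1 and 0.38 with a mean of 50 or more. Immediate early genes were higher at 27 of 41 (median 0.28, adjusted p = 0.0287, or 0.679 with an estimated correlation), with nr4a1 at 3421 and 3191 against 1979 and 2225, jun at 4247 and 3563 against 2763 and 2273, dusp1 at 3900 and 3105 against 2394 and 1554, and dusp2. That call ended under quantile normalisation (median 0.19) and without mutant replicate 1, wild-type replicate 1 or wild-type replicate 2 (medians 0.22, 0.32 and 0.13). Heat shock and unfolded protein response genes fell, at 32 of 48 (median -0.31, adjusted p = 0.0137, or 0.679 with an estimated correlation), with calr3b at 1822 and 2077 against 3043 and 4611, asns at 406 and 506 against 716 and 1058, hspd1 at 2763 and 3571 against 4365 and 5692, and trib3 on the higher side at 2369 and 2101 against 1442 and 1035. Without mutant replicate 2 that call ended (median -0.26), and without wild-type replicate 2 the median was -0.16. Circadian clock genes did not pass (median -0.01, adjusted p = 0.633), with npas2 at 2 and 34 against 102 and 86, nr1d2a at 2901 and 5390 against 2430 and 2131, hlfa and dbpb.

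Genes linked to the mutated locus were compared because a haplotype kept around ccn2a can differ between stocks. With 0 genes past the threshold, the planned share of called genes on chromosome 20 had no value. At an unadjusted p under 0.05, chromosome 20 held 96 of 668 tested genes, or 14.4%, against 12.8% elsewhere (Fisher's exact test, 2-sided, odds ratio 1.15, 95% confidence interval 0.91 to 1.44, p = 0.215, adjusted p = 0.577 over all chromosomes). That share was 3.44% without wild-type replicate 2, 4.94% without mutant replicate 1 and 17.4% without mutant replicate 2. The count of such genes over all chromosomes moved the same way in those fits, so the change is not particular to chromosome 20. With every library kept, the share within 1 Mb of ccn2a was 3 of 34 genes, and within 5 Mb 23 of 156 (Fisher's exact test, p = 0.470). Closest among those 3 was moxd1 (ENSDARG00000031136, 25225112 to 25271878), 115.7 kb from ccn2a by start coordinate, with a log2 fold change of -1.96 (SE 0.203, adjusted p = 0.207). The others, named here after their values were seen, were cyp2v1, at 506 and 415 in the mutants against 283 and 228, and cyp2j20, at 1 and 2 against 20 and 24. They lie in a cluster of similar cytochrome P450 genes that overlap or can share reads, so their values are uncertain.

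**Figure D4:**
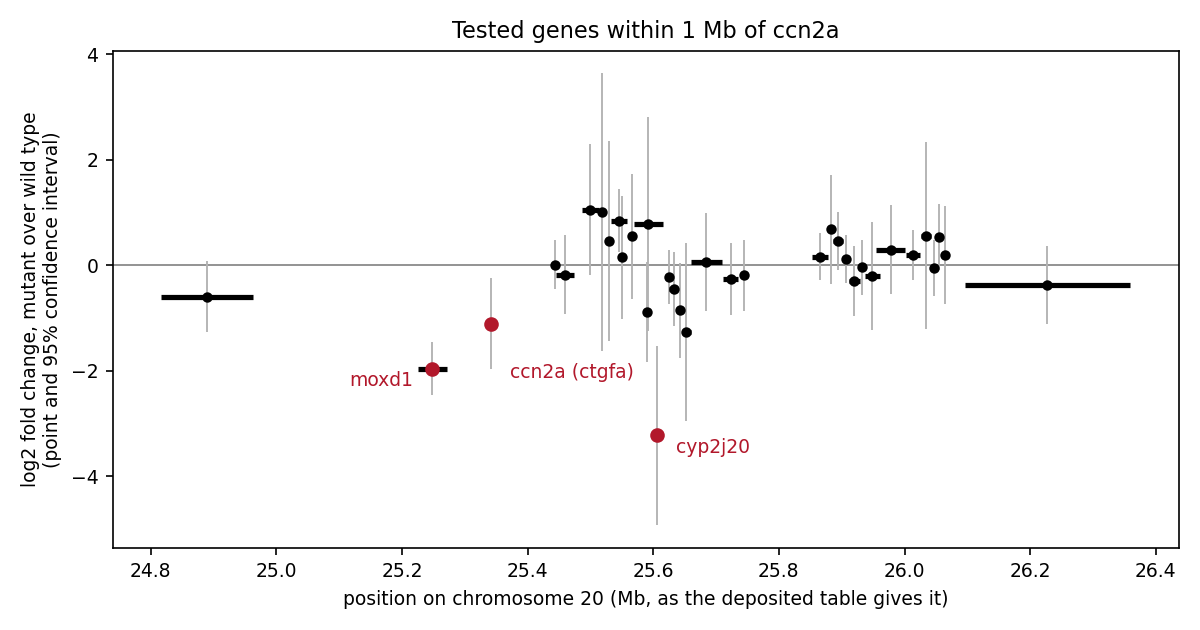
Log2 fold change, mutant over wild type, of each tested gene starting within 1 Mb of ccn2a, with its 95% confidence interval, against position on chromosome 20 in Mb; thick bars span the gene. Red marks ccn2a, moxd1 at -1.96 and cyp2j20 at -3.23.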

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

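The voom fit, the count of genes at an unadjusted p under 0.05 and the share of such genes on chromosome 20 were chosen after the data were seen. With limma, 0 genes passed in the alternatives run, an adjusted p of 0.1 and a 2-fold minimum included, and the count at an unadjusted p was 1701 to 2655 with every library kept and 448 to 2597 with 1 left out (a lone library was assumed to vary like the other group). Over all genes, deviations from the group means did not correlate between the replicates numbered 1 (correlation 0.004). The split by replicate number nevertheless called 6 lists, so a pairing stays open. With the replicate number as a block there were 2655 genes at an unadjusted p under 0.05, against 2145 without it, and 14 lists. Between 12 and 15 lists passed in the other settings that kept every library and the preset correlation, and 10 to 15 with 1 left out; 0 passed with an estimated correlation and 0 with fry. The 14 kept their direction throughout, 7 passed without each library in turn, and 4 (cell cycle, endothelium, oxidative phosphorylation, fatty acid oxidation) passed in all 13 other settings. The log2 fold change of ccn2a was -1.63 to -0.57 with 1 library left out, and its adjusted p 0.241 to 0.868.

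Medians of lists that did not pass changed sign, and the cause was not tested. With a mean of 50 or more they were 0.070 for neutrophils, 0.0078 for smooth muscle, 0.04352 for the circadian clock and -0.50 for liver and plasma proteins. Inflammatory cytokines had -0.051 with no filter and -0.0048 under quantile normalisation, and the circadian clock 0.04266 with a pseudocount of 5 and 0.080 under quantile normalisation. With 1 library left out the ranges were -0.041 to 0.42 for YAP/TEAD targets, -0.33 to 0.042 for neutrophils, -0.11 to -0.039 for inflammatory cytokines, -0.43 to 0.21 for fibroblasts, -0.039 to 0.074 for smooth muscle, -0.18 to 0.63 for atrial genes, -0.19 to 0.39 for the circadian clock and -0.32 to 1.90 for the paralog ctgfb. That was the sole reversal among the 153 genes named beside ccn2a. The called share on chromosome 20 had no value with 0 genes called, and edgeR and DESeq2 on whole reads were not run. Depth was not varied. In simulated data of this size, for genes with a mean of 50 or more, 3.81% of 2-fold, 67.8% of 4-fold and 87.3% of 8-fold changes were called, while none of ctrb1, ANXA1, myo15b, grn1 and MYRFL, more than 8-fold lower here, passed.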

Other observations

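The pathway tests below, the matched random lists, the marker comparison and the search for genes far apart between the genotypes were chosen after the results were seen; for the 14 lists, the leave-one-out values and the other splits were planned. Pathways annotated in the deposited table were tested as further gene groups, some of which share genes with the lists. DNA replication shares pcna and mcm2 to mcm6 with the cell cycle list, so it is not separate support for that list. The broader annotated cell cycle pathway, with 131 tested genes, had a smaller shift, with 92 lower and 39 higher in the mutant. Its median was -0.27 (camera, adjusted p = 0.00369 with the preset correlation, or 0.907 with an estimated one). Of 142 pathways with 10 or more tested genes, 25 passed with the preset correlation (9 higher, 16 lower in the mutant), and 0 with an estimated correlation (smallest adjusted p = 0.907). The count was 14 without mutant replicate 1, 15 without mutant replicate 2, 28 without wild-type replicate 1 and 10 without wild-type replicate 2, and 13 and 10 in the splits that ignore genotype. DNA replication was lower at 33 of 36 genes (median -0.86, adjusted p = 5.26e-07), and its genes with the smallest p were pole, at 154 and 145 in the mutants against 292 and 605 in wild type, pola2, at 238 and 182 against 371 and 553, and pcna, at 2193 and 1809 against 3257 and 5183. Its median was -0.45 without wild-type replicate 2, still called, and it was also called, with a median of 0.44 (adjusted p = 1.28e-05), when mutant replicate 1 and wild-type replicate 2 were set against the others. Ribosome biogenesis, the assembly pathway rather than the ribosomal proteins themselves, was lower at 56 of 68 genes (median -0.35, adjusted p = 9.21e-05), and its genes with the smallest p were the pseudouridine synthase gene dkc1, at 416 and 502 against 849 and 1403, nop58, at 625 and 669 against 1028 and 1461, and on the higher side gtpbp4, at 6019 and 4146 against 2826 and 2541. It was called without each library in turn, with a median of -0.17 without wild-type replicate 2, and it was also called when both replicates numbered 1 were set against both numbered 2 (median -0.17, adjusted p = 0.013). These genes were named after their values were seen.

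The cell cycle list was lower in both mutant libraries; a larger share of cardiomyocytes in the mutant libraries would lower the markers of other heart cells alike. Macrophage, neutrophil, epicardial and fibroblast medians did lie lower (-0.30, -0.13, -0.12 and -0.09, none called), and thrombocyte and lymphocyte medians higher (0.30 and 0.27, neither called). The ventricular sarcomere and calcium-handling list was itself higher, at 27 of 30 genes (median 0.41), which goes with such a share. The erythrocyte and the endothelial and endocardial medians were also higher, at 0.57 and 0.42. All of these were called with the preset correlation (camera, adjusted p = 0.679 each with an estimated correlation). A larger share alone would not raise the erythrocyte and endothelial lists. That argues against a larger cardiomyocyte share as the whole cause unless those genes rose for another reason, and as part of the cause it stays open. The comparison covers that share alone. Other changes in the make-up of the dissected tissue, in which several cell types rise together, were not tested and stay open. Expression level and gene span of the cell cycle genes do not account for their shift, since the list's median lay at percentile 0 of 10000 random lists matched on both (random medians from -0.09 to 0.23 for the central 95%). Genotype and a difference between these particular samples both stay open.

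The oxidative phosphorylation and ribosomal protein lists were higher. Expression level and gene span could account for the ribosomal proteins, whose median lay at percentile 93.8 of the matched lists. The oxidative phosphorylation median, 0.38, lay at percentile 99.99. Its matched lists were themselves higher, with a median of 0.16 (central range 0.03 to 0.29). Expression level and gene span could therefore account for part of that rise. The percentile does not settle the rest, because the random lists were not matched on how genes vary together. The estimated correlation between the oxidative phosphorylation genes was 0.808. In both lists, 1 library carried much of the size. Without mutant replicate 1 the medians were 0.15 for oxidative phosphorylation, down from 0.38, and 0.11 for ribosomal proteins, down from 0.26. Differences between libraries that do not follow genotype cannot be told apart from genotype for the 14 lists as a count: 4 libraries make 3 splits into pairs, too few for a share under 0.05, and another split called 12, while oxidative phosphorylation had its smallest adjusted p, 5.35e-15, in a split that ignores genotype. At the level of genes, 2145 had an unadjusted p under 0.05 by genotype against 117 and 338 in the other splits. Those counts cannot tell genotype from another difference between the samples. The first principal component, with 64.1% of the variance, put the genotypes on opposite sides, and any cause of it would favour that split.

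At 33 tested genes both libraries of 1 genotype lay more than 8-fold below both of the other, with no limit set on the low value itself. The mutants were the low side at 31 of them, and 17 of the 33, or 51.5%, carried clone-type names, against 18.7% of other tested genes (Fisher's exact test, p = 2.31e-05). Chromosome 1, the one with most of them, held 7 of the 33 and 761 of the 16730 tested genes, an excess that was not tested. At an unadjusted p under 0.05 it held 16.6% of its tested genes, against 12.6% elsewhere (Fisher's exact test, p = 0.00223, adjusted p = 0.0581 over all chromosomes). Low counts and library noise without genotype would give similar numbers in the other splits, which gave 2 and 7. With only 3 splits, those counts cannot tell genotype from another difference between the samples. Haplotypes that differ between the 2 stocks, through lost, absent or poorly aligned gene copies, may contribute: 5 neighbouring pairs lay within 2 Mb, against a median of 2 and a central range of 0 to 5 in 10000 random draws. That count, at the edge of the range, leaves it open, and it cannot be told apart from a difference in expression. ANXA1, myo15b, MYRFL and cyp2j20, named in the sections above, are among these 33 genes, so the same limit holds for them. Named after their values were seen, nitr1b was at 54 and 55 in the mutants and at 0 and 0 in wild type, and prokr1a was at 0 and 0 against 13 and 41.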
